A study of Arabidopsis thaliana with 8 samples.

How the data were processed

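Transcript levels were measured with Affymetrix arrays in Arabidopsis thaliana plants of 4 lines, with 2 arrays per line. The labels give the source as 3-week-old plants, while the sample descriptions speak of germinating seedlings. The plants were grown on plates at 23 °C with 16 h of light and 8 h of dark. Total RNA was copied into cDNA and labelled as biotin cRNA by transcription in vitro, and the labels do not name the primer of the first strand. The deposited values are log2 signals, 1 per probe set and array, that the authors made with RMA (version not stated). RMA corrects for background, normalises across arrays and summarises the probes of each probe set. The values were used as deposited, with no further filter. Of 22746 probe sets, 0 were control probe sets, and 1 value was missing. Arrays carry no counts, so their number limits the precision. The signal near the lower end of the scale limits what small changes can show, and larger fold changes from or to a mean under 3 log2 are best read as lower bounds.

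Probe sets were named through the supplied probe table and a table of RefSeq genes on the assembly TAIR10.1, which served only for names, chromosomes and gene order. Of the probe sets, 13513 were listed with 1 gene, 503 with several genes and 8730 were not listed. Unlisted probe sets and those with several genes were tested and counted, but carry no gene name. The 13513 probe sets stood for 13356 genes, and 1580 of them had a symbol other than the locus code. The probe sets of AHG2, ABI1 and ICS1 were not analysed here, since the table names none of these genes.

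Differences between lines were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) on all 8 arrays with 4 groups and no block. The fit had 4 residual degrees of freedom per probe set and prior degrees of freedom of 1.50. Adjusted p values are Benjamini-Hochberg values over all 22746 probe sets in each of the 6 comparisons. A probe set was called when the adjusted p was under 0.05, and calls of at least 2-fold (log2 fold change of at least 1) were also counted. Errors are standard errors from this fit unless SD is stated. Standard deviations cover 2 arrays.

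Gene lists for hormone responses, mitochondrial dysfunction, photosynthesis, oxidative stress, defence, senescence, auxin, RNA tail enzymes and organs were written before the data were examined, as were the comparisons, the tests and most alternatives. The genes of the mitochondrial and plastid genomes and the WRKY, glutathione transferase and heat shock protein families were lists too. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 against all other genes, with 1 probe set per gene. Its p values were adjusted over 66 tests of a list in a comparison. The same test with an estimated correlation, and fry, which asks whether a list moves on balance, were run beside it. A list gene counts as measured only if the probe table names a probe set for it alone. Genes of unlisted probe sets count as not measured, whether or not the array carries them. By this rule no gene was measured in 4 lists (pattern-triggered defence and camalexin, flower and flowering, seed and embryo, and genes with a heat shock protein symbol).

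The overlap of the 3 ahg2-1 lines was set beside that of independent lists and beside 100 simulated draws of unchanged lines against shared wild-type arrays. A change of ahg2-1 was counted as reversed when the line with a second mutation was called in the opposite direction against ahg2-1. Named genes were chosen by a fixed rule. For each of the main comparisons (ahg2-1 against wild type, and each line with a second mutation against ahg2-1) these were the 8 largest rises and the 8 largest falls among calls of at least 2-fold, with non-overlapping arrays and a gene symbol other than the locus code. The rule also took up to 4 members per list with the smallest adjusted p, 8 shared genes per direction, and 4 rises and 4 falls in each other comparison. Genes outside the rule are marked as chosen after their values were seen.

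The method was tested on simulated data with 10 sets of 22746 probe sets and 200 changed ones. It recovered 77.8% of changes of 1 log2 and 91.0% of changes of 2 log2, and 4.47% of its calls were false. The simulated spread came from the model that the fit itself assumes, with independent errors and changes in ahg2-1 only. A low false share was thus built in. These shares check the procedure and need not hold for the real arrays or for comparisons with few changes. Alternatives were a replicate block, fits of only the arrays compared, quantile normalisation again, centring of arrays on the median, a mean signal of at least 5, a trend with a robust prior, array weights, probe sets without suffixes that mark shared sequence, an estimated correlation, separate ahg2-1 arrays in the 2 comparisons of the reversal, and leaving out each array. With 1 array left out, the lone array of a line was taken to vary like the other lines. Clusters of changed genes were tested by 10000 shuffles of the calls over 13217 nuclear genes in chromosome order, again without chromosome 2, and in windows of 50 measured genes.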

Results

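Transcript levels were measured on 8 arrays of Arabidopsis plants, given as 3-week-old plants by their source and as germinating seedlings by their descriptions, 2 for each of 4 lines: wild type (Columbia), ahg2-1, ahg2-1 abi1-1 and ahg2-1 sid2-2. The ahg2-1 mutant is hypersensitive to the hormones abscisic acid (ABA) and salicylic acid (SA) and carries a lesion in a poly(A)-specific ribonuclease. The abi1-1 mutation blocks ABA signalling, and sid2-2 blocks the synthesis of SA. The plants received no treatment. The arrays were alike in signal, with medians of 6.5 to 6.6 log2 and 38.8% to 39.3% of values under 5. Replicates correlated across probe sets at 0.996 to 0.997, where probe sets are not independent replicates. The labels do not say whether replicates came from separate cultures, so p values measure only the spread between these samples.

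The transcripts of the mutated genes AHG2, ABI1 and ICS1 were not analysed here, so the lines were not checked by them. The plot of counts gives the size of the response in each comparison.

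**Figure D1:**
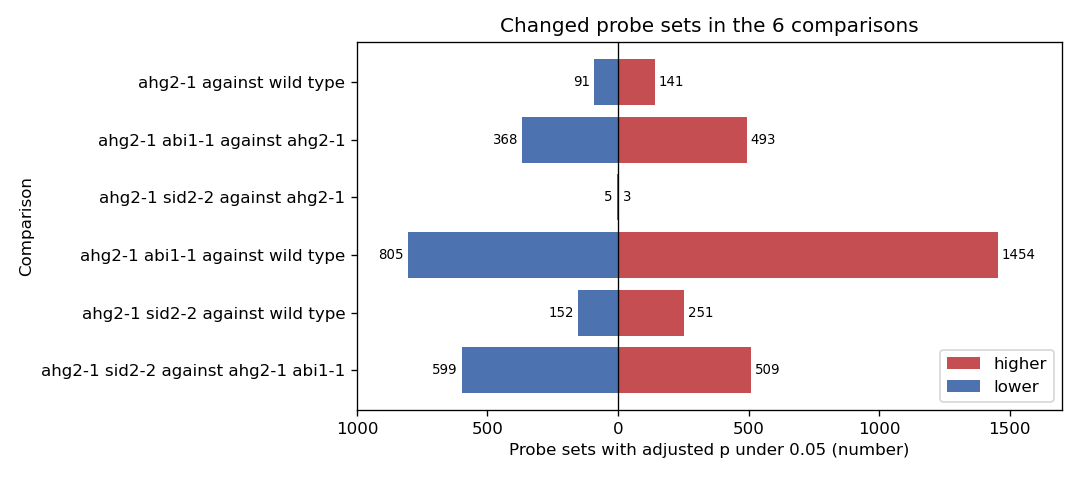
Number of probe sets with an adjusted p under 0.05 in each of the 6 comparisons between lines, with higher ones to the right and lower ones to the left. The ahg2-1 abi1-1 line stood apart from wild type with 1454 higher and 805 lower, while ahg2-1 sid2-2 differed from ahg2-1 in 3 higher and 5 lower.

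The ahg2-1 mutant was compared with wild type to find the transcripts that follow the mutation in plants grown without stress. Transcripts of the mitochondrial genome rose strongly. Most of the measured nuclear genes that respond to failing mitochondria (5 of 17 listed) rose with them. Among these was the alternative NADH dehydrogenase NDB4, but not NDB2. The root hair expansin genes EXPA7 and EXPA18 and the glucanase gene GH9C1 fell. The plastid genome gave no call, and the measured ABA and SA response genes did not rise.

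Of 22746 probe sets, 141 rose and 91 fell, and 77 of the rises and 46 of the falls were at least 2-fold. An unadjusted p under 0.05 was reached by 3377. The count of 232 was lower without any 1 array: 119 without wild type replicate 1, 134 without wild type replicate 2, 45 without ahg2-1 replicate 1, 126 without ahg2-1 replicate 2, 109 without either ahg2-1 abi1-1 array and 122 without either ahg2-1 sid2-2 array.

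Of the 16 measured genes of the mitochondrial genome, 12 rose, 0 fell and 4 did not pass (14 passed adjusted over the list alone), with a median log2 fold change of 4.0. The transcript of cox1, a subunit of cytochrome oxidase, rose from 7.56 ± 0.20 log2 (SD, n = 2) to 13.25 ± 0.25, a log2 fold change of 5.69 ± 0.17 (adjusted p = 5.3e-04). Subunits of complex I rose as well, nad6 by 5.67 ± 0.14, nad9 by 4.63 ± 0.26, nad7 by 4.34 ± 0.29 and nad4L by 4.27 ± 0.13. Genes of cytochrome c maturation rose by 5.20 ± 0.19 for ccmB and 4.70 ± 0.24 for ccmFN2. The maturase matR rose by 4.78 ± 0.32 and cox2 by 3.72 ± 0.42. In wild type ccmFN2, matR and nad7 stood under 3 log2, so their fold changes are best read as lower bounds. The genes nad2 (0.07), nad5 (1.87), mttB (3.31) and ccmFN1 (2.41) did not pass, with adjusted p of 0.933, 0.0607, 0.0983 and 0.390. The 7 probe sets of nad1 ranged from 0.01 to 2.88, and the list used the one at 2.88. Another probe set of nad5, not used, stood at 0.88. The list stood above other genes (camera adjusted p = 9.96e-26, but adjusted p = 0.172 with an estimated correlation), and fry gave an adjusted p of 0.00116. The labels do not name the primer of the first cDNA strand, so these values may reflect tails as well as abundance. Some probe sets of this list match several transcripts. The 11 genes measured without such a suffix had a median of 4.27, and 9 of them rose.

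The 69 measured genes of the plastid genome gave 0 calls (0 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.644). The wild-type arrays differed in these transcripts, which were higher in replicate 1 for 65 of 69 genes, by a median of 1.27 log2. Without wild type replicate 1 the plastid list had a median of 0.76 in ahg2-1, and without wild type replicate 2 a median of -0.45. Nuclear photosynthesis genes LHCB4.1 (0.01), PSAE-1 (-0.07) and PSAN (-0.08) did not pass, and 0 of 3 passed adjusted over the list alone (camera adjusted p = 0.371).

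**Figure D2:**
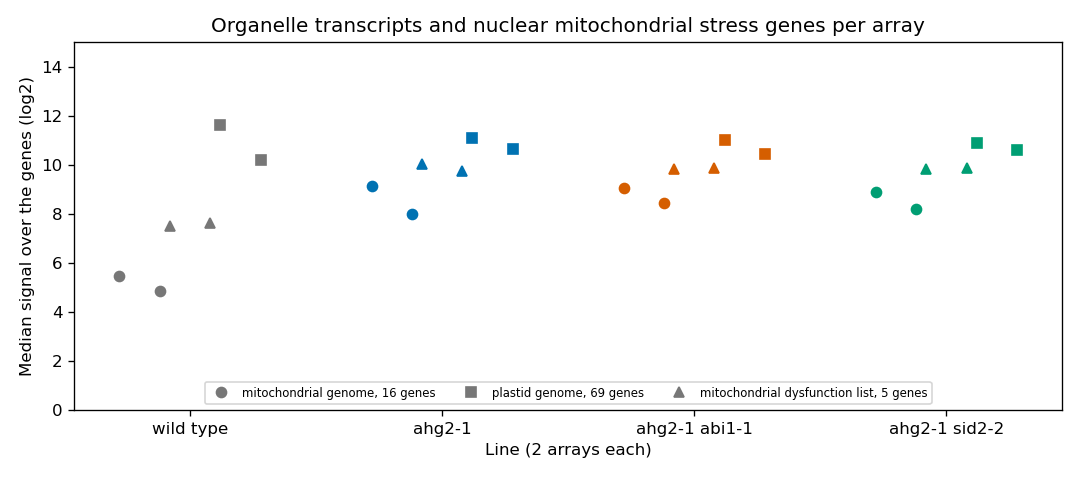
Median log2 signal over 16 genes of the mitochondrial genome (circles), 69 genes of the plastid genome (squares) and 5 nuclear genes of the mitochondrial dysfunction list (triangles) on each of the 8 arrays. The mitochondrial medians were 5.49 and 4.85 in wild type and lay between 8.02 and 9.14 in the 3 mutant lines, while the plastid medians of the mutants lay between those of the wild-type arrays.

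Only 5 of 17 nuclear genes of the mitochondrial dysfunction response had a probe set named for them. Of these, 4 rose and 1 did not pass (4 passed adjusted over the list alone), with a median of 3.27. AT5G09570 rose from 4.95 ± 0.40 (SD, n = 2) to 10.85 ± 0.05, a log2 fold change of 5.89 ± 0.19 (adjusted p = 6.2e-04). The alternative NADH dehydrogenase NDB4 rose by 3.47 ± 0.06 (adjusted p = 2.1e-04), AT2G21640 by 3.27 ± 0.20 and the heat shock protein AT5G51440 by 1.51 ± 0.20, while NDB2 did not pass (0.15, adjusted p = 0.453). In wild type NDB4 stood at 1.75 log2, at the lower end of the scale, so its fold change is best read as a lower bound that its error does not cover. The list stood above other genes (camera adjusted p = 1.48e-10, but adjusted p = 0.117 with an estimated correlation). Outside the list, NDB3, a relative of these dehydrogenases, rose by 4.95 ± 0.16. Among 13 glutathione transferases, GSTU25 (2.28 ± 0.28) and GSTU22 (0.97 ± 0.10) rose, 0 fell and 11 did not pass (3 passed adjusted over the list alone, camera adjusted p = 0.707). The calls of AT5G51440, GSTU25 and ASPGB1 ended when the arrays were quantile normalised again.

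**Figure D3:**
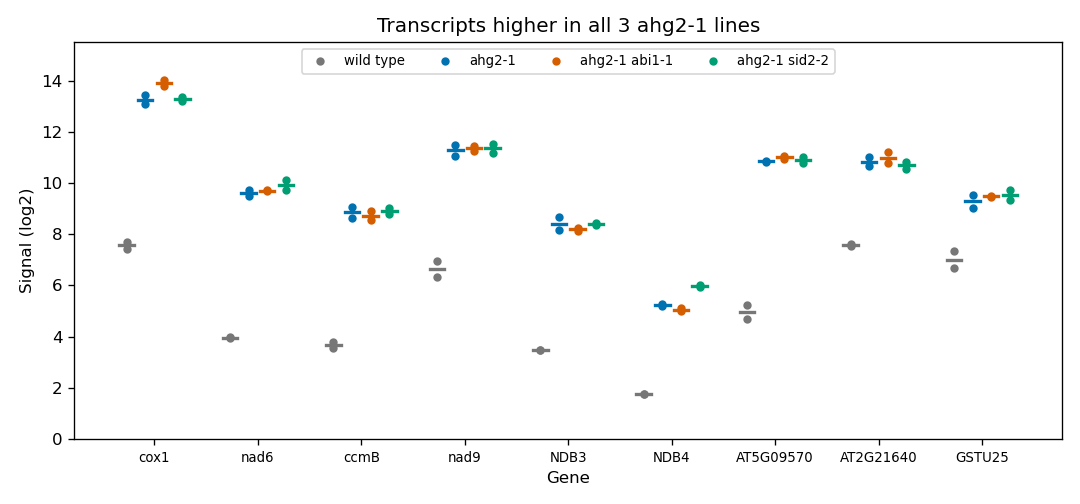
Log2 signal of 9 transcripts in the 4 lines, with a point per array and a bar at the mean of 2 arrays. In each of the 3 mutant lines both arrays lay above both wild-type arrays, for cox1 at means of 13.25 to 13.92 against 7.56.

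Among falls of at least 2-fold, only 5 genes met the naming rule. The root hair expansins EXPA7 and EXPA18 fell, with log2 fold changes of -2.01 ± 0.18 and -1.91 ± 0.13, and the glucanase GH9C1 fell by 1.49 ± 0.09. In the mutant these transcripts lay near the lower end of the scale, at 1.72 log2 for EXPA7. Of 3 measured root markers, 2 fell and PYK10 did not pass (-0.02, adjusted p = 0.946), with 2 passing adjusted over the list alone. The list stood below other genes (camera adjusted p = 1.5e-04, but adjusted p = 0.117 with an estimated correlation). The asparaginase ASPGB1 fell by 1.40 ± 0.17 and the ATP sulphurylase APS4 fell by 1.14 ± 0.12, while its relative APS3 rose by 0.73 ± 0.10. The carboxypeptidase scpl40 passed at -0.78 ± 0.08, but from 2.88 to 2.09 log2, where small changes are not resolved. The subtilase SBT3.12 rose by 0.81 ± 0.09.

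The hormone lists were thinly covered by the probe table, which named probe sets for 5 of 41 ABA genes, 3 of 30 SA genes and 4 of 24 jasmonate and ethylene genes. Of the ABA genes COR47 fell by 0.65 ± 0.08 (adjusted p = 0.0419), and COR15A, COR15B, LEA4-5 and LTI30 did not pass (2 passed adjusted over the list alone). The ABA list had a median of -0.57 and stood below other genes (camera adjusted p = 1.5e-04, but adjusted p = 0.269 with an estimated correlation). The SA genes GRX480, SAG101 and WRKY53 did not pass (0 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.355). The jasmonate and ethylene genes PDF1.2, PDF1.2b, JMT and THI2.1 did not pass (2 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.428). The senescence genes SAG29 (-1.47) and WRKY6 (-0.54) did not pass (2 adjusted over the list alone). The auxin genes GH3.3, IAA29 and WES1 gave 0 calls (0 adjusted over the list alone, camera adjusted p = 0.908), as did 6 WRKY genes (1 adjusted over the list alone, camera adjusted p = 0.371). The oxidative stress gene STZ (-0.03) and the deadenylase genes AT3G58560 (0.18) and AT3G58580 (0.12) did not pass (0 adjusted over the list alone in each list).

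The ahg2-1 abi1-1 line was compared with ahg2-1 to ask which of its transcripts need ABA signalling. The mitochondrial transcripts stayed high. A separate and larger group of genes changed, many of them on chromosomes 4 and 5, led by a gene of glucosinolate synthesis that was low in every other line. None of the 5 measured ABA response genes was called.

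In this comparison 493 probe sets rose and 368 fell, and 138 rises and 180 falls were at least 2-fold. With arrays centred on the median, 398 of 853 calls were rises, 46.7% in place of 57.3%. The count of 861 was 531 without either wild-type array, 198 without ahg2-1 replicate 1, 174 without ahg2-1 replicate 2, 469 without ahg2-1 abi1-1 replicate 1 and 532 without either ahg2-1 sid2-2 array.

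The glucosinolate gene AOP3 rose from 2.83 ± 0.11 log2 (SD, n = 2) to 10.72 ± 0.03, a log2 fold change of 7.89 ± 0.06 (adjusted p = 1.9e-06). In ahg2-1 AOP3 and XTH33 stood under 3 log2, so their fold changes are best read as lower bounds. The subtilase SBT3.12 rose by 2.90 ± 0.09 and the disease resistance gene LOV1 by 2.02 ± 0.14. Further rises were XTH33 at 3.02 ± 0.43, the cytochrome P450 gene CYP71B22 at 2.46 ± 0.33, the allantoinase ALN at 1.90 ± 0.18, the peroxidase Prx37 at 1.69 ± 0.25 and the phosphatase SAL2 at 1.5 ± 0.12. The subtilase SBT4.12 (-3.04 ± 0.31), the methionine sulphoxide reductase MSRB5 (-2.76 ± 0.20) and the chitinase ChiC (-1.94 ± 0.23) fell most among called genes that met the naming rule. MOB1-like (-1.32 ± 0.17), APS3 (-1.23 ± 0.10), CHIL (-1.18 ± 0.13), APL3 (-1.14 ± 0.12) and the farnesol dehydrogenase FLDH (-1.13 ± 0.08) fell too. The rise of GSTU22 in ahg2-1 was reversed, with a log2 fold change of -0.63 ± 0.10 (adjusted p = 0.0400). The calls of XTH33, Prx37 and GSTU22 ended with array weights, and that of Prx37 also with quantile normalisation again.

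Of the 176 measured nuclear genes that changed at least 2-fold, 126 lay on chromosomes 4 and 5, that is 71.6% (exact 95% interval 64.3% to 78.1%), against 37.2% of the measured genes. Chromosome 4 held 66 of them and chromosome 5 held 60, while chromosomes 1, 2 and 3 held 16, 9 and 25. In gene order, 5 of 262 windows of 50 measured genes held more changed genes than the rest, 4 on chromosome 4 and 1 on chromosome 5. AOP3, ChiC and the transcription factor gene MYC3 (1.39) lay in these windows, the last chosen after its values were seen. Every fall of at least 2-fold named above lay on chromosomes 4 or 5, as did the rises AOP3, SBT3.12, ALN, Prx37 and SAL2. No test separated position on these chromosomes from effects of ABA signalling. The rises XTH33, CYP71B22 and LOV1 lay on other chromosomes.

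**Figure D4:**
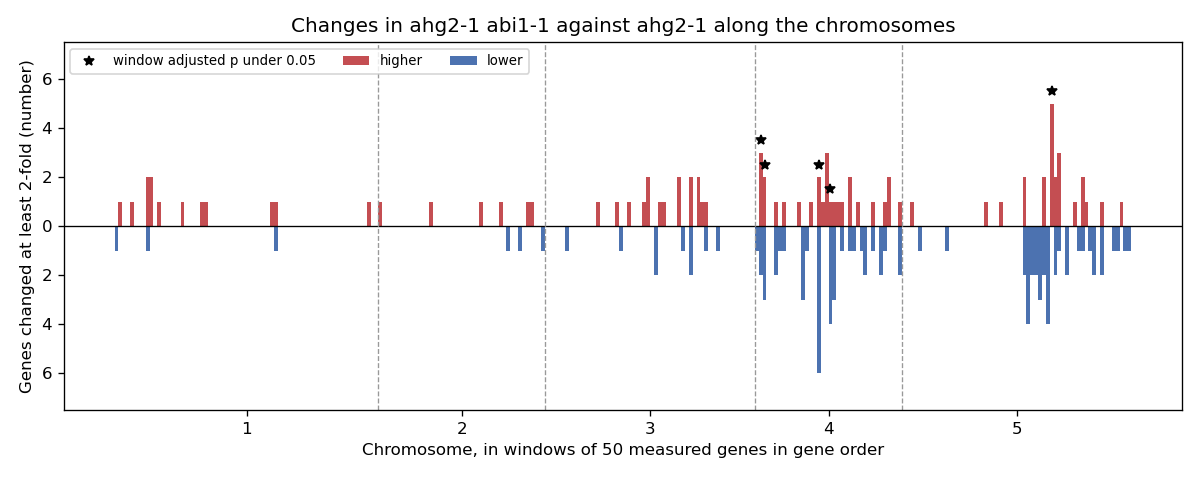
Number of genes that changed at least 2-fold in ahg2-1 abi1-1 against ahg2-1, in windows of 50 measured genes along chromosomes 1 to 5, with rises above and falls below 0. Stars mark the 5 windows with an adjusted p under 0.05, and chromosomes 4 and 5 hold 126 of 176 changed genes.

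The mitochondrial genome gave 0 calls of 16 (0 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.99), and cox1 changed by 0.67 (adjusted p = 0.110). The mitochondrial dysfunction list gave 0 of 5 (0 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.371). The ABA genes gave 0 calls of 5 (3 adjusted over the list alone), with COR15A at -1.15, LEA4-5 at -0.89 and LTI30 at -0.75 against COR15B at 0.58. Their median was -0.75 (camera adjusted p = 0.00566, but adjusted p = 0.392 with an estimated correlation). The jasmonate and ethylene list had a median of -0.38 (0 of 4 called, 0 adjusted over the list alone, camera adjusted p = 0.0369, but adjusted p = 0.269 with an estimated correlation). The plastid list had a median of -0.11 (0 of 69 called, 0 adjusted over the list alone, camera adjusted p = 1.2e-05, but adjusted p = 0.717 with an estimated correlation). The SA genes had a median of 0.36 (camera adjusted p = 0.565), and SAG29 did not pass (-2.68, adjusted p = 0.0594).

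The ahg2-1 sid2-2 line was compared with ahg2-1 to ask which of its transcripts need SA. The lines were nearly alike. The mitochondrial response was kept, and the defensin genes PDF1.2 and PDF1.2b, markers of jasmonate and ethylene signalling, were higher without passing on their own. The SA gene GRX480 was lower without passing.

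Here 3 probe sets rose and 5 fell, with 1 rise and 5 falls of at least 2-fold, while 1365 reached an unadjusted p under 0.05. The count of 8 was 1 without either wild-type array, either ahg2-1 array or either ahg2-1 abi1-1 array, 0 without ahg2-1 sid2-2 replicate 1 and 22 without ahg2-1 sid2-2 replicate 2. None of the 8 met the naming rule, so those with a locus are given by it, chosen after their values were seen. AT3G05950 fell by 2.82 ± 0.08 (adjusted p = 0.00231) and AT5G58840 fell by 1.04 ± 0.05. Both were high only in ahg2-1, AT3G05950 at 5.48 ± 0.16 (SD, n = 2) against 2.65 in wild type, 2.69 in ahg2-1 abi1-1 and 2.66 in ahg2-1 sid2-2. AT5G14610 fell by 2.08 ± 0.10 and AT5G26270 fell by 1.51, while AT4G16230 rose by 0.66 (adjusted p = 0.0472).

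Of the 4 jasmonate and ethylene genes, 0 were called over all probe sets and 3 passed adjusted over the list alone. PDF1.2 stood at 11.36 ± 0.60 log2 (SD, n = 2) against 7.91 ± 0.68 in ahg2-1, a log2 fold change of 3.45 ± 0.57 (adjusted p = 0.350). PDF1.2b gave 2.86 ± 0.29 (adjusted p = 0.129) and JMT 1.3 ± 0.21 (adjusted p = 0.350), while THI2.1 gave -0.37. The list had a median of 2.08 and stood above other genes (camera adjusted p = 5.3e-05, but adjusted p = 0.117 with an estimated correlation), and fry gave an adjusted p of 0.00572. PDF1.2b was called when only probe sets with a mean of at least 5 were tested. Its probe set carries a suffix for shared sequence, so PDF1.2 and PDF1.2b may not be separate values in this list. The SA genes had a median of -0.25 (0 of 3 called, 1 adjusted over the list alone, camera adjusted p = 0.0157, but adjusted p = 0.231 with an estimated correlation), with GRX480 at -0.75. The auxin genes had a median of -0.62 (0 of 3 called, 0 adjusted over the list alone, camera adjusted p = 4.0e-04, but adjusted p = 0.149 with an estimated correlation), with GH3.3 at -0.67 and IAA29 at -0.62. The mitochondrial genome gave 0 of 16 (0 adjusted over the list alone) and a median of 0.05 (camera adjusted p = 0.908), and the ABA list 0 of 5 (0 adjusted over the list alone) and a median of -0.11 (camera adjusted p = 0.882). The plastid list had a median of -0.09 (camera adjusted p = 0.0269, but adjusted p = 0.841 with an estimated correlation). The zinc finger gene STZ, at 1.61, did not pass (adjusted p = 0.723).

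**Figure D5:**
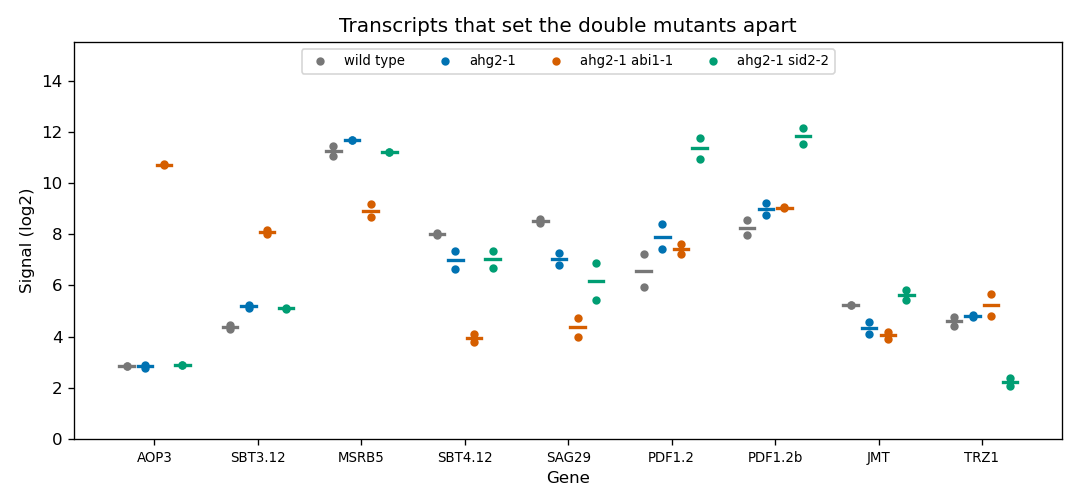
Log2 signal of 9 transcripts in the 4 lines, with a point per array and a bar at the mean of 2 arrays. AOP3 was high in ahg2-1 abi1-1 alone, at 10.72 against 2.83 to 2.89 in the other lines, and PDF1.2 stood highest in ahg2-1 sid2-2, at 11.36.

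Against wild type, the ahg2-1 abi1-1 line showed the mitochondrial response and falls of 4 of 5 measured ABA response genes. In all, 1454 probe sets rose and 805 fell, and 253 rises and 353 falls were at least 2-fold. With arrays centred on the median, 1020 of 2015 calls were rises, 50.6% in place of 64.4%. The count of 2259 was 915 without wild type replicate 1, 997 without wild type replicate 2 and 1079 without ahg2-1 abi1-1 replicate 1. Of 5 ABA genes, LEA4-5 (-2.18), COR15A (-1.73), LTI30 (-1.20) and COR47 (-0.85) fell and COR15B (0.29) did not pass (4 adjusted over the list alone). The list had a median of -1.20 (camera adjusted p = 5.1e-05, but adjusted p = 0.253 with an estimated correlation). Among genes that met the naming rule, SAG29 (-4.14 ± 0.52), SBT4.12 (-4.07 ± 0.31), QQS (-3.29 ± 0.34) and MSRB5 (-2.33 ± 0.20) fell most. JMT fell by 1.19 ± 0.21. AOP3 rose by 7.87 ± 0.06, cox1 by 6.36 ± 0.17, nad6 by 5.75 ± 0.14 and matR by 5.43 ± 0.32, of which AOP3 and matR stood under 3 log2 in wild type and give lower bounds. The mitochondrial genome gave 14 rises of 16 (15 adjusted over the list alone) and a median of 4.11 (camera adjusted p = 3.1e-13, but adjusted p = 0.283 with an estimated correlation). The mitochondrial dysfunction list gave 4 rises of 5 (4 adjusted over the list alone, camera adjusted p = 1.7e-05, but adjusted p = 0.117 with an estimated correlation). GSTU25, GSTU27 and GSTU18 rose among 13 glutathione transferases.

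Against wild type, the ahg2-1 sid2-2 line showed the mitochondrial response and a rise of defensins. In all, 251 probe sets rose and 152 fell, and 82 rises and 62 falls were at least 2-fold. With arrays centred on the median, 196 of 388 calls were rises, 50.5% in place of 62.3%. The count of 403 was 165 without wild type replicate 1, 152 without wild type replicate 2, 188 without either ahg2-1 array, 167 without either ahg2-1 abi1-1 array, 64 without ahg2-1 sid2-2 replicate 1 and 162 without ahg2-1 sid2-2 replicate 2. PDF1.2 rose by 4.78 ± 0.57 (adjusted p = 0.0293) and PDF1.2b by 3.60 ± 0.29 (adjusted p = 0.0115). The PDF1.2b probe set carries a suffix for shared sequence, so these rises may not be separate. The jasmonate and ethylene list gave 2 rises of 4 (2 adjusted over the list alone) and a median of 2.17 (camera adjusted p = 9.3e-04, but adjusted p = 0.149 with an estimated correlation). TRZ1, a tRNA 3' processing nuclease gene, fell by 2.38 ± 0.30 (adjusted p = 0.0340), and XTH18 fell by 1.66 ± 0.24. The calls of TRZ1 and XTH18 ended when the arrays were quantile normalised again. The mitochondrial genome gave 13 rises of 16 (14 adjusted over the list alone) and a median of 4.01 (camera adjusted p = 1.1e-22, but adjusted p = 0.195 with an estimated correlation). COR47 (-0.77), EXPA18 (-2.19) and EXPA7 (-2.01) fell. The ABA list gave 1 fall of 5 (2 adjusted over the list alone) and a median of -0.77 (camera adjusted p = 7.7e-04, but adjusted p = 0.320 with an estimated correlation).

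The lines with a second mutation were also compared with each other, which sets sid2-2 against abi1-1, each with any linked differences. In ahg2-1 sid2-2, 509 probe sets were higher and 599 lower than in ahg2-1 abi1-1, and 198 of the higher and 137 of the lower were at least 2-fold. The count of 1108 was 660 without either wild-type array, 573 without either ahg2-1 array, 515 without ahg2-1 abi1-1 replicate 1, 193 without ahg2-1 sid2-2 replicate 1 and 500 without ahg2-1 sid2-2 replicate 2. PDF1.2 was higher by 3.94 ± 0.57, PDF1.2b by 2.81 ± 0.29 and JMT by 1.58 ± 0.21, so that 3 of 4 jasmonate and ethylene genes were higher (3 adjusted over the list alone, camera adjusted p = 7.5e-06, but adjusted p = 0.117 with an estimated correlation). The PDF1.2 call ended with the replicate block (adjusted p = 0.0549), with only the arrays compared (adjusted p = 0.0552) and without any 1 array of these lines. Since the PDF1.2b probe set carries a suffix for shared sequence, PDF1.2 and PDF1.2b may not count as separate genes here. The ABA gene LTI30 was higher by 1.25 ± 0.19 and NDB4 by 0.94 ± 0.06. AOP3 (-7.83), SBT3.12 (-2.98), XTH33 (-3.10), TRZ1 (-3.01) and GRX480 (-0.94) were lower, with AOP3, XTH33 and TRZ1 under 3 log2 in ahg2-1 sid2-2. AOP3 and SBT3.12 lie on chromosome 4, PDF1.2 on chromosome 5 and TRZ1 next to ICS1. For these, effects of SA or ABA were not told apart from linked differences. PDF1.2b and JMT lie on chromosomes 2 and 1.

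The changes shared by the 3 ahg2-1 lines answer which transcripts follow ahg2-1 whatever the second mutation. Of the 232 probe sets called in ahg2-1, 171 (73.7%) were called in the same direction in both other lines, 114 higher and 57 lower. Independent lists of these sizes would share 0.121, and unchanged lines set against shared wild-type arrays shared at most 1 in 100 draws. Those draws held no changed probe sets, so they cannot show how much of the overlap the shared arrays give. All 3 comparisons use the same wild-type arrays, so part of the overlap may come from them. The count was 101 without wild type replicate 1, 113 without wild type replicate 2, 37 without ahg2-1 replicate 1, 89 without ahg2-1 replicate 2, 80 and 84 without ahg2-1 abi1-1 replicate 1 and 2, and 47 and 63 without ahg2-1 sid2-2 replicate 1 and 2. Higher in all were cox1, nad6, ccmB, NDB3, matR, ccmFN2, nad9 and nad7, with nad6 at 5.67, 5.75 and 5.96 and NDB3 at 4.95, 4.73 and 4.92. Lower in all were EXPA7, EXPA18, GH9C1, APS4, scpl40 and COR47, the only genes with a symbol that met the rule for falls, though scpl40 stayed under 3 log2 throughout.

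Reversal asks whether blocked ABA signalling or SA synthesis undoes an ahg2-1 change. In ahg2-1 abi1-1, 32 of 232 changes were reversed, 11 rises and 21 falls, and 12 went further. In ahg2-1 sid2-2, 4 were reversed, 3 rises and 1 fall, and 0 went further. Against wild type, 190 and 188 of the 232 were called again, and the changes kept slopes of 0.87 and 0.92 on those of ahg2-1. Both sides of these slopes share the wild-type arrays, through which simulated unchanged lines correlated at 0.50. Both sides of a reversal share the ahg2-1 arrays, which by itself gives calls apart by chance. With separate ahg2-1 arrays, 9 of 126 and 4 of 45 changes were reversed in ahg2-1 abi1-1, and 1 each time in ahg2-1 sid2-2. The counts were 50 and 11 with a trend and robust prior, 52 and 7 with a mean of at least 5, and 2 and 0 with only the arrays compared. APS3 (0.73 in ahg2-1, then -1.23), on chromosome 4, and GSTU22, on chromosome 1, were reversed in ahg2-1 abi1-1. AT3G05950 and AT5G58840 were high only in ahg2-1 and lay near the wild-type level in both lines with a second mutation. They therefore single out neither ABA signalling nor SA synthesis. Without 1 array the count in ahg2-1 abi1-1 was 14 and 10 for wild type replicate 1 and 2, 6 and 16 for ahg2-1 replicate 1 and 2, 12 for either ahg2-1 abi1-1 array and 17 for either ahg2-1 sid2-2 array. In ahg2-1 sid2-2 it was 1 without any 1 of the 6 arrays of the other lines, 0 without ahg2-1 sid2-2 replicate 1 and 3 without replicate 2.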

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

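Of the tests in this part, those on the mitochondrial transcripts, on the chromosomes, on the direction of changes in the enriched windows, on pairs without chromosome 2 and on the excess of rises were chosen only after the result was seen.

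The 12 probe sets listed for a mitochondrial gene together with another gene stood outside the gene comparisons and showed a signal above wild type. In ahg2-1, 11 of them lay above both wild-type arrays and 6 passed, with a median log2 fold change of 2.46 (range 0.02 to 6.27). For 45.3% of all probe sets, the ahg2-1 arrays lay wholly above or wholly below the wild-type arrays.

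4 named genes differed between the lines with a second mutation and were picked because their values lay on opposite sides of ahg2-1. None of the differences from ahg2-1 passed by itself, and those of PDF1.2, TRZ1 and JMT in ahg2-1 abi1-1 were near their error. JMT was 1.58 ± 0.21 higher in ahg2-1 sid2-2 than in ahg2-1 abi1-1 (adjusted p = 0.0226), from differences of 1.3 and -0.28. LTI30 differed by 1.25 ± 0.19 (adjusted p = 0.0287), from 0.50 and -0.75. PDF1.2 differed by 3.94 ± 0.57 (adjusted p = 0.0262), from 3.45 and -0.49. TRZ1 differed by -3.01 ± 0.30 (adjusted p = 0.0115), from -2.59 and 0.41. In each case both arrays of one line lay beyond both of the other, as they did for 47.2% of all probe sets. The PDF1.2 and TRZ1 calls ended with only the arrays compared (adjusted p = 0.0552 and 0.0780). That of PDF1.2 also ended with the replicate block (adjusted p = 0.0549) and without any 1 array of these lines. That of TRZ1 also ended without ahg2-1 sid2-2 replicate 1.

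The mitochondrial transcripts rose by a median of 4.0 log2 in ahg2-1 and stayed high in the other mutant lines. A general gain of organelle RNA in labelling is argued against by the plastid list, whose median was 0.12 (0.24 for the 26 genes under 10 log2 in wild type), and 0.76 without wild type replicate 1, against 4.32 for the mitochondrial list then. Labelling as the only difference, in plants otherwise like wild type, is argued against by the nuclear mitochondrial dysfunction list, with 4 of 5 measured members called. The limit for this was set with the calls known. Nuclear calls cannot show whether labelling raised the mitochondrial values as well, so that stays open. A nuclear copy of the mitochondrial genome on chromosome 2 stays open: genes measured without a shared-sequence suffix had a median of 4.27, but probe sequences were not used here. A candidate explanation, not tested here, is that the lesion in the ribonuclease leaves mitochondrial transcripts more abundant or with longer tails. Abundance and tails were not separated, since the primer of the first strand is not stated.

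Changed genes of ahg2-1 abi1-1 lay closer together than calls shuffled over all chromosomes. Chromosomes 4 and 5 held 71.6% of the genes changed at least 2-fold, which is consistent with segments of another accession that came in with abi1-1. Tandem gene families as the whole cause are argued against by 87 pairs 6 to 20 genes apart, above the highest of the shuffles (59, permutation p = 1e-04, the smallest they can give). In ahg2-1 against wild type 10 such pairs stood against a mean of 3.28 (permutation p = 0.003), but 7 of them lay on chromosome 2, and 3 remained without it, against a mean of 2.00 (permutation p = 0.32). For ahg2-1 abi1-1 all 87 remained. The shuffles moved calls between chromosomes, so the large share on chromosomes 4 and 5 by itself raises the number of pairs. Pair counts therefore do not show closeness within a chromosome apart from that share. Of neighbouring genes, 9 pairs changed together against a mean of 2.32 in the shuffles (permutation p = 6e-04), with the same limit. Beside ahg2-1 the excess was larger as a difference (6.68 against 0.79 pairs), which grows with the number of called genes, and not as a ratio (3.88 against 4.77), which rests on 1 pair in ahg2-1. The test had not fixed which to use, so it left the segments open. Weaker binding through sequence differences would lower signals, but only 53.6% of the changed genes in the enriched windows were lower (exact 95% interval 33.9% to 72.5%). The rises argue against it as the whole cause in these windows, though the limits set for the test left it undecided. For the falls it stays open, and no test separated segments from effects of ABA signalling.

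Rises outnumbered falls in ahg2-1 abi1-1 against wild type, at 64.4%, but among changes of at least 2-fold 353 were falls and 253 rises, so the excess lay in smaller changes. Probe sets near the lower end of the scale as the source are argued against by 61.2% of rises without those of a mean under 5. The median signals of the arrays of these lines differed by 1.42 times the largest gap between replicates. Limits of 1 and 3 times were set after the values were seen. A ratio over 3 was to count against scaling between arrays, although scaling itself moves these medians. The test therefore cannot decide, and scaling stays open. Centring the arrays sets the balance of rises and falls by itself and decides nothing. A small rise of many transcripts in this line remains open too and was not tested.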

How the results depend on the processing

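Of the alternatives in this part, only leaving out the loci of chromosomes 4 and 5 and the mitochondrial list without shared-sequence suffixes were chosen after the result was seen.

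Of 199 results for named genes in a comparison, none changed direction while called. Calls were lost for 42 with only the arrays compared, 12 with the replicate block, 6 with quantile normalisation again and 3 with array weights. They were gained for 2 with a mean of at least 5. The replicate block, centring on the median and the trend with a robust prior gained 1 each. Over all settings that leave out 1 array, 144 values lost a call and 1441 kept their side of the threshold. Such fits have fewer residual degrees of freedom.

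With only the arrays compared, the counts were 20 (ahg2-1 against wild type), 186 (ahg2-1 abi1-1 against ahg2-1), 0 (ahg2-1 sid2-2 against ahg2-1), 491 (ahg2-1 abi1-1 against wild type), 12 (ahg2-1 sid2-2 against wild type) and 171 (between the lines with a second mutation). Shared changes were then 7, and 2 (ahg2-1 abi1-1) and 0 (ahg2-1 sid2-2) were reversed. These fits have fewer arrays. At least 2-fold, the counts were 123, 318, 606, 144 and 335 in the same order without ahg2-1 sid2-2 against ahg2-1, 87 were shared and 12 reversed in ahg2-1 abi1-1, by construction. An adjusted p under 0.01 in each line left 43 shared.

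With array weights the counts were 354 for ahg2-1 against wild type, 495 for ahg2-1 abi1-1 against ahg2-1 and 756 for ahg2-1 sid2-2 against wild type. With a trend and robust prior, 23 differed between ahg2-1 sid2-2 and ahg2-1, and 50 (ahg2-1 abi1-1) and 11 (ahg2-1 sid2-2) were reversed. With a mean of at least 5, 52 and 7 were reversed and the root list was too small to test. With separate ahg2-1 arrays, 9 and 1 (replicate 1 against wild type) and 4 and 1 (replicate 2) were reversed. The cause was not tested. Without loci on chromosomes 4 and 5, ahg2-1 abi1-1 differed from ahg2-1 in 459 and 1 was reversed in ahg2-1 sid2-2. Fewer genes and all probe sets of unknown position remain.

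With an estimated correlation, the list tests for ahg2-1 gave adjusted p of 0.269 (ABA), 0.117 (mitochondrial dysfunction), 0.117 (root markers) and 0.172 (mitochondrial genome), and 0.117 for jasmonate and ethylene in ahg2-1 sid2-2 against ahg2-1. The cause was not tested.

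Without 1 array the counts ranged from 45 (ahg2-1 replicate 1) to 134 (wild type replicate 2) for ahg2-1 against wild type, 174 (ahg2-1 replicate 2) to 721 (ahg2-1 abi1-1 replicate 2) for ahg2-1 abi1-1 against ahg2-1, and 0 (ahg2-1 sid2-2 replicate 1) to 22 (ahg2-1 sid2-2 replicate 2) for ahg2-1 sid2-2 against ahg2-1. Against wild type they ranged from 915 to 1882 for ahg2-1 abi1-1 and from 64 to 188 for ahg2-1 sid2-2, and from 193 to 869 between those lines. Shared changes ranged from 37 to 113, and reversed ones from 6 to 17 (ahg2-1 abi1-1) and 0 to 3 (ahg2-1 sid2-2). The list tests named here for ahg2-1 against wild type, and jasmonate and ethylene for ahg2-1 sid2-2 against ahg2-1, kept their calls: ABA 1.15e-07 to 0.00124, mitochondrial dysfunction 5.80e-11 to 5.98e-08, root markers 3.04e-06 to 0.00191, mitochondrial genome 8.29e-28 to 9.06e-20, and jasmonate and ethylene 4.12e-05 to 0.00204. Over all lists and comparisons, 13 tests without 1 array lost a call, 10 gained one and 4 changed direction.

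4 list tests changed direction without 1 array, over ranges of 1.82e-13 to 0.776 (plastid, ahg2-1 against wild type), 1.31e-17 to 0.0277 (plastid, ahg2-1 abi1-1 against wild type), 2.78e-14 to 0.556 (plastid, ahg2-1 sid2-2 against wild type) and 0.00137 to 0.970 (ABA, ahg2-1 sid2-2 against ahg2-1). Without wild type replicate 1 the plastid list was higher in ahg2-1 abi1-1 (adjusted p = 0.0277) and ahg2-1 sid2-2 (adjusted p = 4.1e-08) against wild type, and without wild type replicate 2 it was lower in ahg2-1 (adjusted p = 2.5e-09). The wild-type arrays differed by a median of 1.27 log2 in this list. Without ahg2-1 replicate 2 the ABA list was higher in ahg2-1 sid2-2 than in ahg2-1 (adjusted p = 0.00381), and the cause was not tested.

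For the pairing of replicate numbers, the residuals of equal numbers correlated between lines at 0.03, -0.05, 0.25, 0.37, 0.01 and -0.06. Not every value was over 0.1, so the numbers were not used as pairs, but a shared effect of the number in some lines is not excluded. With a replicate block, ahg2-1 sid2-2 differed from ahg2-1 in 1 probe set and 1 change was reversed in ahg2-1 sid2-2. The other counts stayed within 1.5 times the main ones, at 242, 685, 2250, 332 and 881, with 160 shared and 42 reversed in ahg2-1 abi1-1. The block ended 12 calls of named genes: ASPGB1, COR47, AT5G51440, GSTU22 and scpl40 in ahg2-1 against wild type, XTH33 and GSTU22 in ahg2-1 abi1-1 against ahg2-1, TRZ1, XTH18, APS4 and scpl40 in ahg2-1 sid2-2 against wild type, and PDF1.2 between the lines with a second mutation.

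At 38.8% to 39.3% of values under 5 log2, small changes near the lower end of the scale are not resolved.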

Other observations

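Of the tests in this part, those of AT1G47400 and BHLH101, the groups of gene symbols, the gene order around ICS1 and the chromosome 2 window were chosen only after the results were seen.

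2 genes were picked for high values with a wide spread in ahg2-1. AT1G47400 rose by 5.28 log2 (adjusted p = 0.0347), from 4.87 to 10.15 ± 1.16 (SD, n = 2), and lay at 7.27 in ahg2-1 abi1-1 and 7.88 in ahg2-1 sid2-2, neither of which differed from ahg2-1 past the threshold (adjusted p = 0.0757 and 0.575). The iron regulator BHLH101 stood 4.35 above wild type without passing (adjusted p = 0.0975).

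A probe set listed for several genes was at 8.86 log2 in wild type and 9.06 in ahg2-1 abi1-1, but at 2.80 in ahg2-1 and 2.35 in ahg2-1 sid2-2. Its fall in ahg2-1 was -6.06 (adjusted p = 0.00155).

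TRZ1 lies next to ICS1, the gene altered by sid2-2, in the gene order of TAIR10.1. Its measured neighbours IQD31 (-0.06) and QKY (0.07) did not pass in ahg2-1 sid2-2 against wild type, with adjusted p of 0.800 and 0.830, while TRZ1 changed by -2.38.

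Among 44 groups of genes whose symbols start with the same letters, with at least 5 measured genes each, the symbols in CYP, which join cytochrome P450 and cyclophilin genes, stood higher in ahg2-1 sid2-2 than in ahg2-1, with 24 of 26 genes above 0 and a median of 0.18 (camera adjusted p = 1.4e-05 over 132 tests, adjusted p = 0.884 with an estimated correlation). The SWEET sugar transporters did so with 14 of 14 genes and a median of 0.17 (camera adjusted p = 0.00164, adjusted p = 0.884 with an estimated correlation). The symbols in PDF did so with 7 of 7 genes and a median of 0.26 (camera adjusted p = 6.3e-04, adjusted p = 0.884 with an estimated correlation). In ahg2-1 against wild type, the symbols in XTH stood lower, with a median of -0.37 (camera adjusted p = 0.0141, adjusted p = 0.884 with an estimated correlation), as did those in PRA, with a median of -0.14 (camera adjusted p = 0.0338, adjusted p = 0.884 with an estimated correlation). In these comparisons only 1 gene of the 5 groups, in XTH, passed on its own.

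On chromosome 2, a window that includes the region of the nuclear mitochondrial copy held 7 called genes in ahg2-1 against wild type, among them AT2G07676 (3.01) and AT2G07707 (2.94). Their probe sets carry the suffix for shared sequence.

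In each of the 4 lines replicate 1 had higher medians than replicate 2 for the mitochondrial and the plastid lists, at 5.49 and 4.85 for the mitochondrial and 11.65 and 10.18 for the plastid list in wild type.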
